A study of Mus musculus with 48 samples.

How the data were processed

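Polyribosomes were pulled down with an antibody against the haemagglutinin tag from nucleus accumbens of mice with Cre driven by Drd1 or Adora2a and carrying tagged Rpl22, per the labels, with 4 punches of 14 gauge per mouse and 4 mice pooled per library. Per the labels, RNA was taken on day 10 of fentanyl abstinence and libraries were made from 10 ng of RNA with the Smart-Seq v4 kit, which keeps no strand and adds no molecular identifiers. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.8 to GRCm38 and assigned to genes with HTSeq, whose version, strand setting and annotation release are not stated. The deposited counts are whole numbers of reads over exons per gene, with no normalization, for 54838 Ensembl genes and 5 summary lines per library. The summary lines held 22.93 ± 3.77% of all reads (SD, n = 48, 17.72 to 32.57%) and were left out of every total. Reads outside exons made up 13.08 ± 1.46% in D1 and 7.966 ± 0.843% in D2 libraries, and reads aligned to several places 8.373% and 6.223%, so that genes with near-identical copies lose reads or share them. Alignment to several places, overlapping genes on either strand and short exons can thus lower or mix the counts of single genes. Since reads from amplified libraries are not independent molecules, floors cover counting error only, while the t intervals cover the spread between libraries.

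Gene symbols, coordinates and transcript sequences came from GENCODE M21 on GRCm38, in which 54723 identifiers had a symbol and 115 did not. For each named gene the share of exonic bases overlapped by other genes and the share of its transcript stretches of 50 bases that another gene also holds were computed. Libraries were grouped by the labels into 8 groups of 6, and depth is the sum of reads over genes. The numbers of the replicates were tested as pairs and did not pair the libraries. No library was left out, and no pair among 120 pairs of replicates was a copy of another.

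Tests used edgeR 4.0.16 in R 4.3.3 with TMM scaling, filterByExpr (count minimum 10, total minimum 15), the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. D1 and D2 libraries were fitted apart for fentanyl against water over both sexes, in each sex, for the difference between the sexes, and for females against males in water. All 48 libraries were fitted together for D1 against D2 in water and for the difference in fentanyl response. The filter left 16782 genes in D1, 17706 in D2 and 18270 in all libraries. All tests were two-sided, intervals are 95% t intervals on the residual degrees of freedom, and log2 CPM used a prior count of 2. Each p-value refers to pools of 4 mice, not to single mice.

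The 37 gene lists covered neuron types, other cell types, blood, activity and stress genes, opioid and dopamine signalling, channels, receptors, synapse, matrix, chromatin, mitochondria, ribosome, unfolded protein, cholesterol and sex-linked genes. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. For every list that passed, its median, mean and test had the same sign. The lists, comparisons, tests, alternatives and the rule for named genes were chosen before the data were examined. Where genes passed with a mean CPM of at least 2 and a proper symbol, the rule named up to 12 each way for fentanyl over both sexes, 10 each way for D1 against D2 and 5 each way elsewhere. Where too few passed, it named those with the smallest p, 10 each way over both sexes and 5 elsewhere, as not passing. It also named up to 4 members of each list, all opioid genes, Drd1, Drd2, Adora2a and Rpl22.

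The alternatives were DESeq2 1.42.0, limma voom with quality weights, RLE scaling, no filter, a block for replicate number, a covariate of non-neuronal markers, 2 surrogate variables from sva 3.50.0, all 48 libraries in 1 fit, an estimated correlation, Spearman correlation and a mean CPM of at least 10 for agreement between fold changes. Alternatives added after the data were seen were a covariate of the other cell type's markers, fits without single libraries and a permutation of list scores. Permutation tests were exact where the number of arrangements allowed and otherwise used 100000 random draws, except that correlations of fold changes used 100 permutations of treatment labels, and 100 drawn splits of the libraries were refitted beside the real one. Tested on simulated data of the same design with 50 genes changed by each fold, edgeR recovered 48% of genes changed 1.25-fold in D1, 72% at 1.5-fold, 88% at 2-fold and 100% at 4-fold, with 10 false calls among 168. In D2 the shares were 52%, 76%, 86% and 100% with 4 false calls among 170, and for the difference between cell types 24%, 54%, 80% and 98% with 6 among 135. A further list of genes was raised slightly, and its calls counted as neither recovered nor false. Simulated counts were drawn independently for each gene, without spread shared between genes of a library, so these shares may overstate recovery in the real libraries. All these genes changed at once, and with many calls the adjustment is milder than where no gene passes. The shares therefore do not give the recovery of a few changed genes.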

Results

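Messenger RNA bound to tagged ribosomes was sequenced from the nucleus accumbens of mice, a ventral striatal region of reward and motivation whose main neurons are medium spiny neurons of 2 kinds. D1 libraries came from mice carrying Drd1-Cre, which is active in neurons with the dopamine D1 receptor, and D2 libraries from mice with a Cre driver of Adora2a, the adenosine receptor gene active in neurons with the dopamine D2 receptor. In both lines Cre switches on a haemagglutinin-tagged copy of the ribosomal protein Rpl22, so that polyribosomes of the chosen neurons can be pulled down (RiboTag). Male and female mice were in abstinence from fentanyl, a mu-opioid agonist, and taken on day 10, or belonged to water groups, in a study of negative affective behaviours during abstinence. Each of the 8 groups of cell type, sex and treatment held 6 libraries, 48 in all, and each library pooled 4 mice, so that a p-value below speaks of pools of mice. The libraries held 29921831 reads in genes on average (SD 4178951, range 20211543 to 42584762). D2 libraries were deeper, at 32690424 ± 3511626 reads (SD, n = 24), against 27153238 ± 2712615 in D1 libraries (SD, n = 24). Group means ran from 26579713 ± 3572165 reads in D1 female water to 27873552 ± 2228281 in D1 male fentanyl. In D2 they ran from 31038338 ± 2317387 reads in female water to 33617714 ± 1909073 in female fentanyl (SD, n = 6). Gene levels below are in CPM, reads scaled to library size with the TMM factors of all 48 libraries. They are given with the SD between libraries, and fold changes are log2 with the standard error (SE).

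The comparison of D1 with D2 libraries in the water groups asks how well each pull-down captured its neurons. Drd1, the dopamine D1 receptor gene (ENSMUSG00000021478, chromosome 13, 54051183 to 54055705), stood at 490 ± 60.4 CPM in D1 and 50.9 ± 6.93 in D2 libraries (n = 12 each), a log2 difference of 3.27 (SE 0.076, edgeR adjusted p = 2.8e-35). Drd2, the dopamine D2 receptor gene (ENSMUSG00000032259, chromosome 9, 49340627 to 49408177), was at 58.3 ± 19.2 CPM in D1 and 418 ± 34.6 in D2 (log2 −2.84, SE 0.147, edgeR adjusted p = 1.3e-21). Adora2a, an adenosine receptor gene (ENSMUSG00000020178, chromosome 10, 75316877 to 75334784), was at 105 ± 49.2 CPM in D1 and 941 ± 107 in D2 (log2 −3.15, SE 0.244, edgeR adjusted p = 1.85e-15). All 10 genes of the D1 neuron list were higher in D1, among them Isl1, a homeobox factor of the direct pathway (44.1 ± 2.68 against 2.15 ± 0.478 CPM). Pdyn, the dynorphin precursor, was at 632 ± 114 against 37.2 ± 8.22 CPM, and Tac1, the substance P precursor, at 1820 ± 177 against 503 ± 58.7. All 9 genes of the D2 neuron list were lower in D1, including Penk, the enkephalin precursor, at 2350 ± 574 against 16500 ± 1720 CPM, and the orphan receptor Gpr6, with a log2 difference of −2.70. Both lists passed camera (D1 list adjusted p = 1.35e-56, D2 list 7.99e-19) and held with an estimated correlation (adjusted p = 4.43e-10 and 0.0018). Rpl22, the gene of the tagged protein (ENSMUSG00000028936, chromosome 4, 152325742 to 152334071), stood at 36.6 ± 7.75 CPM in D1 and 33.8 ± 2.93 in D2 libraries (log2 0.11, edgeR adjusted p = 0.176). With a score of non-neuronal markers as a covariate its difference was 0.91 (edgeR adjusted p = 0.0452). The vascular markers in that score ran from 0.758 to 1.687 log2 CPM in D1 and from 4.386 to 5.243 in D2 libraries (n = 24 each). Because the score nearly repeats the cell type, fits of D1 against D2 with it cannot separate cell type from non-neuronal content.

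**Figure D1:**
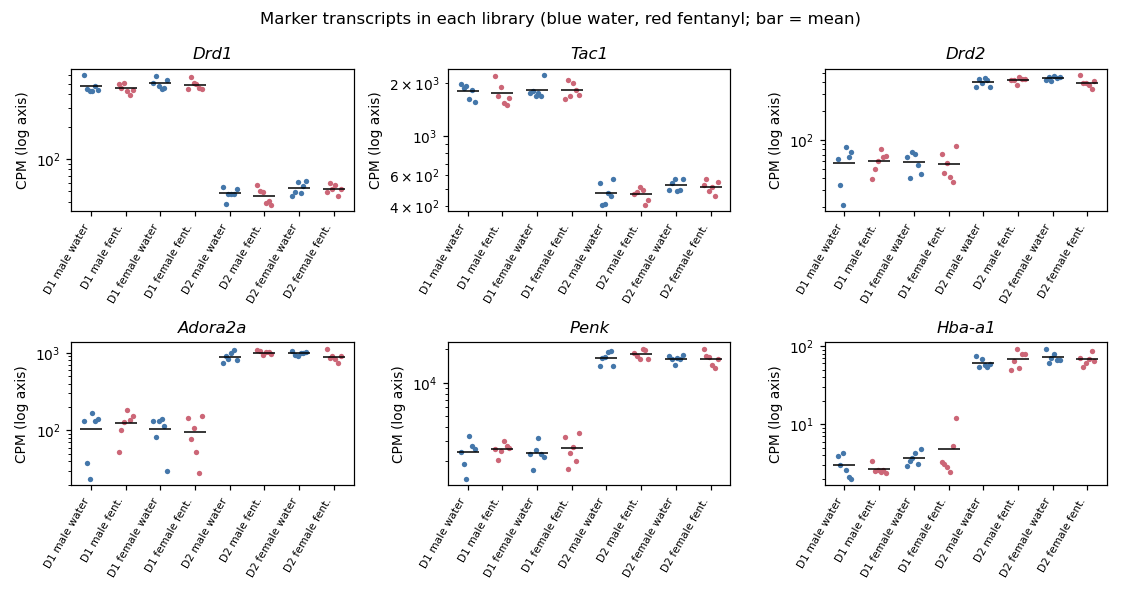
Level of 6 marker genes in each of the 48 libraries, in CPM on a log axis, by cell type and sex, with water in blue, fentanyl in red and the group mean as a bar. In water libraries Drd1 lay at 490 CPM in D1 and 50.9 in D2, while Drd2 and Adora2a lay at 58.3 and 105 CPM in D1 and at 418 and 941 in D2.

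Of 18270 genes tested, 4900 were higher and 4858 lower in D1 than in D2 water libraries by edgeR at an adjusted p under 0.05. The largest differences among the named genes in the D1 direction were in Ms4a15 (log2 5.35), Arhgap36 (5.03, 13.5 ± 3.79 against 0.43 ± 0.239 CPM), Isl1 (4.35) and Pdyn (4.09). They also took in Pvalb, the parvalbumin gene of fast-spiking interneurons (3.86), Cox6a2 (3.58), Slc35d3 (3.57), Cort, the cortistatin precursor (3.45), Nxph2 (3.34) and Igsf1 (3.28). Ms4a15 varied from 0.0979 to 20 CPM between the D1 water libraries. In the D2 direction the named gene with the largest difference was Vtn, vitronectin, at 1.38 ± 0.441 CPM in D1 and 138 ± 28.4 in D2 (log2 −6.63). The others were Kcnj8 and Abcc9, which form the potassium channel of pericytes (−5.93 and −5.30), the class II genes H2-Ab1 (−5.93) and H2-Aa (−5.60), Slc38a5 (−5.92), Pglyrp1 (−5.78), Higd1b (−5.63), Ctla2a (−5.26) and Myl9 (−5.25). Of the exonic 50-base stretches of Ctla2a, 30.8% also occur in another gene, so its value is uncertain. With a score of non-neuronal markers as a covariate, 1402 genes passed, 925 higher and 477 lower in D1, and Ms4a15 and Igsf1 no longer did (edgeR adjusted p = 0.125 and 0.0691). Since the score nearly repeats the cell type, this fall does not show how many differences come from other cells.

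Transcripts of other cell types differed between the pull-downs in both directions. All 12 vascular genes were lower in D1, with a mean log2 difference of −3.71 (SE 0.0959), among them Cldn5, the tight junction gene of brain endothelium, at 3.75 ± 1.28 against 57.9 ± 7.46 CPM. All 5 blood genes were lower in D1 (mean −4.57, SE 0.131), with the beta-globin gene Hbb-bs at 6.93 ± 3.06 against 258 ± 45.4 CPM, although 65.5% of its 50-base stretches are shared with another globin gene. Lower in D1 were also 10 of 12 astrocyte genes, including the gap junction gene Gja1 (log2 −2.85), and all 12 oligodendrocyte genes, including the myelin enzyme Cnp (−1.22). So were 9 of 10 microglial genes, including Ctss (−1.89), and 5 of 7 genes of oligodendrocyte precursors, including Cspg4 (−2.92), with 1 precursor gene higher. In contrast all 8 cholinergic interneuron genes were higher in D1 (mean 2.04, SE 0.155), including the vesicular glutamate transporter Slc17a8 (3.07). All 8 excitatory pallial genes were higher too. Of 11 GABA interneuron genes 9 were higher and 1 lower in D1, with Sst, somatostatin, at 491 ± 120 against 74.7 ± 13.2 CPM. Camera called the vascular (adjusted p = 1.15e-47), blood (1.16e-24), astrocyte (5.82e-17), oligodendrocyte (1.03e-11), precursor (0.000765), cholinergic (7.08e-05) and GABA interneuron lists (1.73e-11), and these held with an estimated correlation (adjusted p = 4.49e-07, 4.3e-06, 0.00245, 0.0194, 0.0106, 0.0272 and 0.00399). The microglial (camera adjusted p = 0.000765) and pallial lists (4.21e-05) had adjusted p = 0.209 and 0.0774 with an estimated correlation. None of the 5 ependymal genes passed (camera adjusted p = 0.869). With the non-neuronal score as a covariate, which is built from 5 of these lists, the oligodendrocyte, precursor and microglial lists turned direction (camera adjusted p = 0.479, 0.881 and 0.000525), and the astrocyte and cholinergic lists had 0.967 and 0.652. These changes decide nothing about the lists, because the score nearly repeats the cell type.

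**Figure D2:**
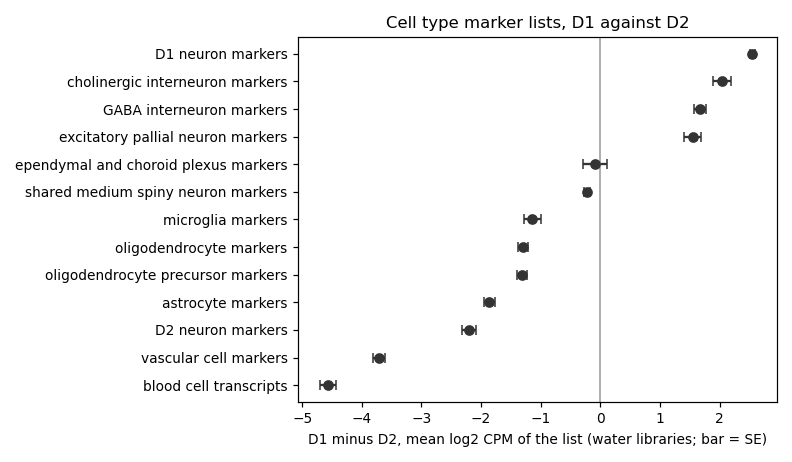
Difference between D1 and D2 water libraries in the mean log2 CPM of each list of cell type markers, with the standard error as a bar. The lists ran from −4.57 for blood and −3.71 for vascular genes to 2.04 for cholinergic interneuron genes and 2.55 for D1 neuron genes.

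Of 34 voltage-gated and other channel genes 22 were higher and 1 was lower in D1, including Kcnc1 (log2 0.91). Of 22 glutamate receptor genes 17 were higher and 2 lower, including Grin3a (1.96) and Grik1 (2.08), and of 14 GABA receptor genes 10 were higher and 1 lower, including Gabrg1 (1.11). The synaptic vesicle list had 17 of 22 genes higher and 1 lower, with Syt1, the calcium sensor of release, at 0.72, and the neuropeptide list 12 of 18 higher and 3 lower. The dendrite, spine and actin list had 20 of 34 genes higher and 6 lower, including Arhgap32 (0.86). Camera called the channel (adjusted p = 1.14e-06), glutamate receptor (0.000456), GABA receptor (3.91e-06), vesicle (5.13e-05), neuropeptide (1.61e-09) and dendrite lists (0.000181), with adjusted p = 0.0424, 0.0171, 0.00714, 0.0106, 0.00112 and 0.0245 with an estimated correlation. With the non-neuronal score as a covariate, which nearly repeats the cell type, the glutamate receptor, GABA receptor, vesicle and dendrite lists had camera adjusted p = 0.243, 0.215, 0.0689 and 0.0727. The opioid, endocannabinoid and chromatin lists had 0.881, 0.0738 and 0.246. The kinesin and microtubule list had 22 of 29 genes higher and 1 lower, including Map1a (0.59), and the chromatin list 21 of 32 higher and 3 lower, including Ep300 (0.70). The endocannabinoid list had 5 of 9 higher and 1 lower, including the cannabinoid receptor Cnr1 (1.74), and the opioid list 5 of 8 higher and 3 lower. These 4 lists passed camera at an adjusted p of 0.000102, 0.000456, 0.0316 and 0.0354, against adjusted p = 0.0725, 0.136, 0.0941 and 0.0547 with an estimated correlation. Oprm1, the mu-opioid receptor gene, was at 4.34 ± 1.02 CPM in D1 and 2.23 ± 0.478 in D2 libraries (log2 0.95). Oprk1, the kappa receptor gene, was at 65.3 ± 8.2 and 41.3 ± 4.84 CPM (0.66), and Pnoc, the nociceptin precursor, at 8.24 and 1.13 (2.89). Oprl1 was also higher in D1 (0.53), and Oprd1, the delta receptor gene (−0.71), and Pomc (−0.47) were lower.

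The interferon response list had 10 of 14 genes lower in D1 and 2 higher, including Isg15 (log2 −2.63). The extracellular matrix list had 10 of 19 lower and 6 higher, including Sparc (−3.43) and Bcan (−2.17), and the respiratory chain list 18 of 44 lower and 1 higher, including Sdhb (−0.37). Camera gave adjusted p = 0.000151, 0.000456 and 0.0252 for these lists, and 0.103, 0.0844 and 0.605 with an estimated correlation. All of them turned direction and none passed with the non-neuronal score as a covariate. The other 12 lists did not pass camera. Among them 6 of 12 genes shared by both medium spiny neuron types were lower in D1 (adjusted p = 0.0802), 5 of 7 nuclear noncoding RNAs (0.0871) and 7 of 13 mitochondrially encoded genes (0.083). The immediate early list had 2 of 16 genes higher and 5 lower (0.0871), with Jun at 41.9 ± 6.06 CPM in D1 and 303 ± 27.4 in D2 and Nr4a2 higher in D1 (log2 2.29). The glucocorticoid list had 2 of 11 higher and 6 lower (0.0734) and the heat shock list 3 of 12 higher and 4 lower (0.492). The circadian list had 4 of 16 higher and 5 lower (0.915), and the dopamine and cAMP list 7 of 23 higher and 9 lower (0.986). The ribosomal protein list had 10 of 46 higher and 1 lower (0.432) and the unfolded protein list 5 of 18 higher and 8 lower (0.287). The cholesterol list had 7 of 17 higher and 2 lower (0.253), and 0 of the 5 Y-linked and Xist genes passed (edgeR; adjusted p = 0.986 by camera). Adjusted over the list alone the counts were the same, except for 7 lower dendrite genes, 10 lower dopamine and cAMP genes, 5 higher ribosomal genes, and 6 higher and 10 lower unfolded protein genes.

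In D1 neurons, the comparison of fentanyl abstinence with water over both sexes asks which translated transcripts changed in direct-pathway neurons. No gene passed an adjusted p of 0.05 by edgeR among 16782 tested, with 639 at an unadjusted p under 0.05, where evenly spread p-values would give 839. Random splits of the same libraries, drawn after the data were seen, gave a median of 612.5 such genes (303 to 3402). Limma voom called 0 genes (1115 unadjusted), and DESeq2 called 3 (645 unadjusted): Psmd10, Gm13340 and Gm28437, named after their values were seen. Gm28437 was more than 20-fold above the D1 median only in D1 male water 2, D1 male water 6 and D1 female water 2, and Gm13340 only in D1 female water 2 and D1 female water 6. They share 100% and 30% of their 50-base stretches with other genes. Among the named genes the smallest p belonged to Rprm, reprimo, a p53 target linked to cell cycle arrest (ENSMUSG00000075334, chromosome 2, 54084093 to 54085552), at 35 ± 3.77 CPM with fentanyl and 42.5 ± 9.26 with water in males and 32.8 ± 5.49 and 44.8 ± 6.09 in females (log2 −0.36, SE 0.0872, edgeR unadjusted p = 0.000348, adjusted p = 1). Kcnj11, which encodes the pore of the ATP-sensitive potassium channel, was at 21.6 ± 1.46 against 23.8 ± 1.83 CPM in males and 22.7 ± 1.05 against 26.3 ± 1.1 in females (log2 −0.18). The other named genes with lower values were Rcor3, a REST corepressor (−0.44), Slc1a3, the astrocytic glutamate transporter (−0.33), and Mir124-2hg (−0.23). They also took in Cntnap1, a paranodal protein (−0.20), Hipk4 (−0.19), Iqce (−0.22), Fancf (−0.23) and Styx (−0.43). Those with higher values were Smg8, a factor of nonsense-mediated decay (0.27, SE 0.0714), Syne2 (0.26), Tpx2, a spindle factor (0.39), Zfp438 (0.33), Recql (0.25), Smpd2, a neutral sphingomyelinase (0.24), Oser1 (0.18) and Ywhaq, a 14-3-3 protein (0.19), and all 18 stood at edgeR adjusted p = 1. Recql, Oser1, Ywhaq and Styx share 47.9%, 44%, 38.1% and 54.7% of their 50-base stretches with another gene, and their values are uncertain.

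Hnrnpu, a nuclear matrix and RNA-binding protein, and Ddx3y, a Y-linked RNA helicase, complete the named genes of D1, and both stood out in few libraries. Hnrnpu (log2 1.71, edgeR adjusted p = 1) stood at 22.2 CPM in D1 male fentanyl 5, where the other libraries of the group lay at 1.81 to 2.85, and at 31.3 in D1 female fentanyl 4. Ddx3y stood at 3.51 CPM in D1 female fentanyl 5 and at 0.105 to 0.313 in the other libraries of that group (edgeR adjusted p = 1). Of the 4 genes given in every comparison, Drd1 had a log2 difference of −0.05 (95% interval −0.18 to 0.08), Drd2 0.01, Adora2a 0.05 and Rpl22 −0.15 (edgeR unadjusted p = 0.0877). The median half-width of the 95% intervals was 0.19 on the log2 scale, and the intervals of 95.4% of genes lay within a 2-fold change in either direction. In simulated data of this design edgeR recovered 72% of genes changed 1.5-fold and 88% of those changed 2-fold. These shares may overstate recovery here, since the simulated genes varied independently of each other. They also rest on 168 simulated calls, which eased the adjustment, so they do not give the recovery of a few changed genes.

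**Figure D3:**
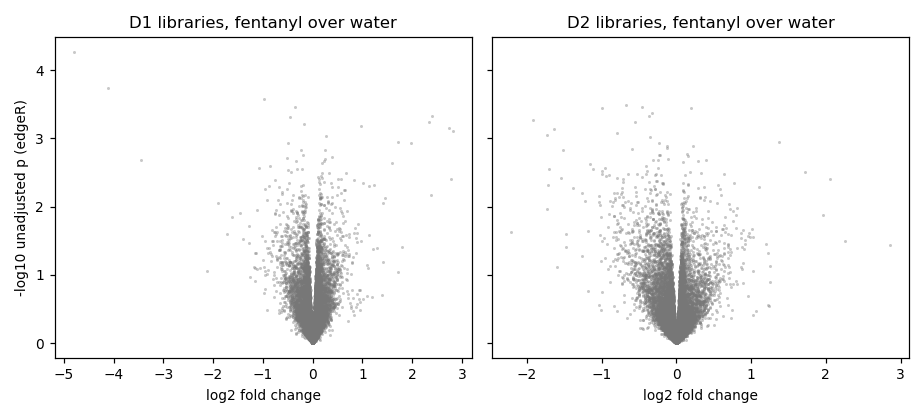
Log2 fold change between fentanyl and water over both sexes for every gene tested, against the negative log10 of the unadjusted edgeR p, with D1 and D2 neurons in separate panels. No gene passed an adjusted p of 0.05 in either panel, and 639 genes in D1 and 783 in D2 had an unadjusted p under 0.05.

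As lists, 6 of 37 passed camera in D1 neurons. Of 34 channel genes 31 lay below 0, with the potassium channel gene Kcna2 at −0.16 and the calcium channel gene Cacna1a at −0.11 (camera adjusted p = 0.000167, and adjusted p = 0.558 with an estimated correlation). Of 46 ribosomal protein genes 44 lay below 0, with Rpl22 at −0.15 (adjusted p = 0.00102, and 0.827 with an estimated correlation). Of 16 immediate early genes 13 lay above 0, with the synaptic gene Arc at 0.35 and the nuclear receptor Nr4a1 at 0.42 (adjusted p = 0.00895, and 0.667 with an estimated correlation). The Y-linked and Xist list (adjusted p = 0.00762), the blood list (0.0271), with Hbb-bs at −0.51, and the nuclear noncoding list (0.0411), with 6 of 7 members below 0 and Neat1 at −0.33, all had adjusted p = 0.558 with an estimated correlation. The other 31 lists had camera adjusted p from 0.0513 to 0.921. Adjusted over the list alone, 7 genes passed by edgeR: Slc1a3 of the astrocyte list, Hbb-bs of the blood list and all 5 members of the Y-linked and Xist list, 4 higher and 1 lower. Without D1 female water 6, the library with the fewest reads, 2 lists passed, and the blood, nuclear noncoding, immediate early and ribosomal lists had camera adjusted p = 0.108, 0.0561, 0.0561 and 0.535. Without D1 female fentanyl 5, which held the most Y-linked reads of the female libraries, the Y-linked and Xist list had camera adjusted p = 0.508.

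The opioid list, which holds the opioid and nociceptin receptors and the precursors of their peptides, had all 8 members above 0 in D1 neurons: Pnoc (log2 0.17), Pomc (0.15), Penk (0.12), Oprm1 (0.11), Oprk1 (0.09), Oprd1 (0.06), Oprl1 (0.05) and Pdyn (0.04). No member passed, with edgeR unadjusted p from 0.206 to 0.684, and camera gave the list an adjusted p of 0.0513 (0.558 with an estimated correlation). Oprk1 and Pdyn lay below 0 with surrogate variables, and Oprd1 with the other cell type's marker score as a covariate. The mean log2 CPM of the list was 5.135 ± 0.0688 with fentanyl and 5.063 ± 0.0621 with water in males (SD, n = 6). In females it was 5.181 ± 0.0732 and 5.046 ± 0.0651. Its difference of 0.10 had a two-sided permutation p of 0.000925 in a test added after the data were seen. Its Benjamini-Hochberg adjusted p was 0.0342 over the 37 lists of this comparison and 0.308 over all 333 tests of the 9 fentanyl comparisons. In males the difference was 0.07 (exact permutation p = 0.0823) and in females 0.14 (exact permutation p = 0.00433). In D2 neurons 4 members lay above and 4 below 0: Pdyn 0.08, Penk 0.06, Pomc 0.04, Oprl1 0.04, Oprd1 −0.02, Oprm1 −0.04, Oprk1 −0.07 and Pnoc −0.10. The D2 list score differed by −0.0025 (permutation p = 0.942), and the difference between cell types was 0.10 (permutation p = 0.0365, adjusted p = 0.765).

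**Figure D4:**
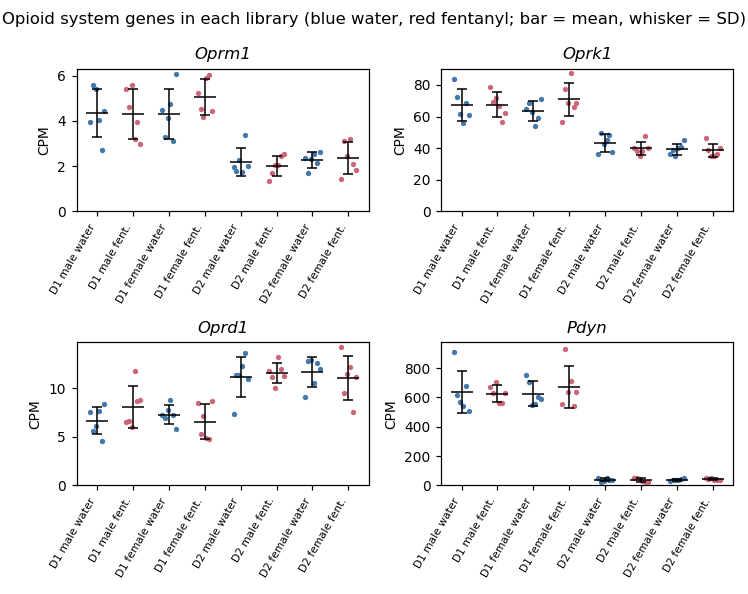
Level of Oprm1, Oprk1, Oprd1 and Pdyn in each library in CPM, by cell type, sex and treatment, with the group mean as a bar and the SD as a whisker. No member passed edgeR in either cell type, and the fentanyl and water libraries overlapped for all 4 genes.

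Split by sex, no D1 gene passed edgeR. In males 464 genes had an unadjusted p under 0.05. DESeq2 called 4 genes (Rcor3, Syne2, Psmd10 and Gm28437) and limma voom 2 (Rcor3 and Syne2). Rcor3 was at 7.33 ± 1.23 CPM with fentanyl and 13.4 ± 0.72 with water in males (log2 −0.87, adjusted p = 0.161 by edgeR, 0.000546 by DESeq2 and 0.0161 by voom). Syne2, a nesprin that links nucleus and cytoskeleton, was at 12.8 ± 0.697 and 9.18 ± 1.04 (0.49, adjusted p = 0.386 by edgeR, 0.0111 by DESeq2 and 0.0259 by voom). Of the exonic 50-base stretches of Rcor3, 16.8% occur in another gene. Zfp438 (0.65), Zbtb34 (0.37) and the pseudogene Ube2n-ps1 (0.51) did not pass any of the 3 tools. In females 964 genes had an unadjusted p under 0.05 DESeq2 called 0 (992 unadjusted) and voom 0 (1193 unadjusted). The named genes of females were Smpd2 (0.41), Tmem199 (0.23), Sipa1l2, a synaptic GTPase activator (−0.44), Depdc5, a GATOR1 subunit that restrains mTORC1 (−0.23), and Ddx3y, all at edgeR adjusted p = 0.807. Between the sexes edgeR called 0 genes (674 unadjusted), voom 0 (1070 unadjusted) and DESeq2 4 (710 unadjusted). Depdc5 (log2 −0.43, DESeq2 adjusted p = 0.00843), Zbtb34 (−0.65, 0.0452), Gm6030 and Ndufb4c, all of whose 50-base stretches occur in another gene, were these 4. Mtch2 (0.45) and Tmtc2 (−0.82) were named without passing. DESeq2 also called Depdc5, Zbtb34, Ndufb4c and Mtch2 between females and males in D1 water. Both comparisons use the same D1 water libraries, so for these genes they are not separate findings.

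In D1 males 15 of 16 immediate early genes lay above 0 (camera adjusted p = 4.11e-09, and adjusted p = 0.284 with an estimated correlation). The mean log2 CPM of that list was 4.894 ± 0.0879 in D1 male water (SD) and 5.148 to 5.205 in the other D1 groups. Of 46 ribosomal genes 45 lay below 0 (2.91e-10) and of 44 respiratory genes 40 (0.000154), both at adjusted p = 0.851 with an estimated correlation. The blood list lay below 0 (0.000342, and adjusted p = 0.284 with an estimated correlation), with a mean log2 CPM of 0.1034 ± 0.192 against 0.5443 ± 0.399 with water (SD). In D1 females 32 of 34 channel genes lay below 0 (5.01e-06), 11 of 12 oligodendrocyte genes above 0 (0.000272) and 23 of 32 chromatin genes below 0 (0.000493), and the Y-linked (0.00232), dendrite (0.0221) and pallial lists (0.0283) also passed. With an estimated correlation the female lists had adjusted p from 0.446 to 0.653. The difference between the sexes in response passed camera for 7 lists. Of the immediate early genes 15 of 16 were lower in the female than in the male response (4.48e-05), and of the ribosomal genes 40 of 46 were higher (4.48e-05). The others were the oligodendrocyte and respiratory (5.27e-05 each), Y-linked (5.4e-05), chromatin (0.000186) and channel lists (0.00245). With an estimated correlation these 7 had adjusted p from 0.577 to 0.789. Without D1 female water 6 the channel difference had adjusted p = 0.203, and without D1 female fentanyl 5 the Y-linked list had 0.361 in females and 0.114 for the difference.

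In D2 neurons no gene passed edgeR over both sexes among 17706 tested, with 783 at an unadjusted p under 0.05, where evenly spread p-values would give 885. Random splits of the D2 libraries gave a median of 793.5 such genes (391 to 3032). DESeq2 called 0 genes (780 unadjusted) and voom 0 (971 unadjusted). Dlx1, a homeobox factor of GABA neuron development (ENSMUSG00000041911, chromosome 2, 71528113 to 71533981), was at 15.1 ± 2.69 CPM with fentanyl and 21.3 ± 5.97 with water in males and at 16.9 ± 2.44 and 22.4 ± 4.34 in females (log2 −0.45, SE 0.111, edgeR unadjusted p = 0.000346, adjusted p = 0.998). Tspan9, a tetraspanin (chromosome 6, 127961396 to 128143594), had a log2 difference of 0.20 (SE 0.0482, edgeR unadjusted p = 0.000358), and Ank3, the ankyrin of the axon initial segment, 0.14. Further named genes with higher values were the actin gene Acta1 (0.22), Tma7 (0.16), Scarf2 (0.40), Arpc5l of the actin-nucleating complex (0.08), Uxt (0.19), Arhgef39 (0.33), Usp13 (0.12) and the pseudogene Rpl7a-ps11 (2.06). Those with lower values were Rrm2, the ribonucleotide reductase subunit (−0.55), Dock1, a Rac activator (−0.36), Acot1 (−0.36), Dbx2 (−0.33), Lix1 (−0.24), Incenp, a chromosomal passenger protein (−0.24), Vps35l (−0.12), Os9, a lectin of protein quality control (−0.12), and Ift74 (−0.12). Drd1 stood at −0.05, Drd2 at −0.03, Adora2a at 0.01 and Rpl22 at 0.02. Of their 50-base stretches Uxt, Tma7, Acot1, Lix1, Vps35l and Rpl7a-ps11 share 38.6%, 21.1%, 19.1%, 16.3%, 19.2% and 100% with another gene, and their values are uncertain. The median half-width of the 95% intervals was 0.15 on the log2 scale, and in simulated data of this design edgeR recovered 76% of genes changed 1.5-fold and 86% of those changed 2-fold. Simulated genes varied independently of each other, so these shares may overstate recovery here too. With 170 simulated calls the adjustment was also milder than where no gene passes.

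Of the 37 lists, 7 passed camera in D2 neurons. All 12 astrocyte genes lay below 0, including the folate enzyme Aldh1l1 (log2 −0.32), the growth factor receptor Fgfr3 (−0.22) and the glial transcription factor Sox9 (−0.20). The mean log2 CPM of the list was 4.709 ± 0.256 with fentanyl against 4.94 ± 0.327 with water in males and 4.943 ± 0.105 against 5.082 ± 0.186 in females (SD, n = 6 each). The astrocyte list had camera adjusted p = 2.33e-07, and adjusted p = 0.618 with an estimated correlation. Of 46 ribosomal protein genes 38 lay above 0 (adjusted p = 0.000203), with Rpl28 at 0.17, and of 44 respiratory genes 37 (0.0012), with the complex I gene Ndufb5 at 0.05, both at adjusted p = 0.914 with an estimated correlation. Of 12 oligodendrocyte genes 10 lay below 0 (adjusted p = 0.0183), with the galactolipid enzyme Ugt8a at −0.31, and of 19 matrix genes 13 (0.0291), with tenascin C, Tnc, at −0.84. Of 14 interferon genes 10 lay above 0 (0.0491), and all 3 lists were at adjusted p = 0.914 with an estimated correlation. The cholinergic list had 5 of 6 members above 0 (adjusted p = 0.0183, and 0.618 with an estimated correlation). Adjusted over the list alone, 1 gene of the interferon list rose by edgeR, the interferon regulatory factor Irf7 (0.63). The other 30 lists had camera adjusted p from 0.067 to 0.962. D2 male fentanyl 1 and D2 female fentanyl 1 stood apart with 6.32% and 6.26% of reads outside exons, and without both, 4 lists passed, and the cholinergic, oligodendrocyte, interferon and matrix lists had adjusted p = 0.0675, 0.163, 0.184 and 0.241.

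Split by sex, no D2 gene passed edgeR. In males 1234 genes had an unadjusted p under 0.05, voom called 0 genes and DESeq2 1, Gm2451, named after its value was seen. Gm2451 is a pseudogene that shares 90.5% of its 50-base stretches with other genes, and it stood at 60.6 CPM in D2 male fentanyl 2 against a D2 median of 1.71. Among the named genes were Lnx1 (log2 −0.73), Dock1 (−0.54), Fam19a5 (0.19) and Emc10 (0.14), all at edgeR adjusted p = 0.571. In females 838 had an unadjusted p under 0.05, and DESeq2 called 4 genes and voom 1. Birc5, survivin, had a log2 difference of −0.82 (adjusted p = 0.374 by edgeR and 0.0297 by DESeq2). Tspan9 was at 25.7 ± 0.907 CPM with fentanyl and 20.6 ± 1.86 with water (0.32, 0.374 and 0.0297), and Ank3 at 210 ± 10.9 and 175 ± 6.54 (0.26, 0.374 and 0.0297, with 0.0393 by voom). Gm28437, far above the D2 median in female fentanyl 1 and female fentanyl 3 among the female libraries, was the other DESeq2 gene, and Rrm2 (−0.81) and Os9 (−0.20) were named without passing. Between the sexes edgeR called 0 genes (1458 unadjusted), voom 0 (1799 unadjusted) and DESeq2 8 (1448 unadjusted). These included Trib3, a pseudokinase of the stress response (log2 −0.61, DESeq2 adjusted p = 0.0111), and Rad1, of the DNA damage clamp (−0.39, 0.0402). The other 6 were Gm28438 and 5 genes that switched on in few D2 libraries and share 77% to 100% of their 50-base stretches with other genes: Gm10925, Gm28437, Gm29216, Gm28661 and Gm7292. Mapk8, the kinase JNK1 (0.42), and Map3k3 (−0.45) stood at edgeR adjusted p = 0.381.

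In D2 males all 12 astrocyte genes lay below 0 (camera adjusted p = 0.000144) and 11 of 12 genes shared by medium spiny neurons above 0 (0.00422), and the nuclear noncoding (0.0363), cholinergic, pallial and dopamine and cAMP lists (0.0494 each) also passed. With an estimated correlation their adjusted p was 0.783, and 0.841 for the dopamine and cAMP list. In D2 females all 9 D2 neuron genes lay below 0 (2.35e-05), with 2 of them passing by edgeR adjusted over the list alone, and the mean log2 CPM of that list was 7.808 ± 0.103 with fentanyl and 7.939 ± 0.0263 with water (SD, n = 6). Of 46 ribosomal genes 42 lay above 0 in D2 females (camera adjusted p = 1.12e-09), of 14 interferon genes 13 (0.00295), and of 12 oligodendrocyte genes 11 below 0 (0.00132). The respiratory (0.00132), channel (0.00198), kinesin (0.00198), vascular (0.00894) and astrocyte lists (0.0142) passed too, and with an estimated correlation all 9 lists of D2 females had adjusted p = 0.593. The D2 neuron list also differed between the sexes in its response (9 of 9 lower in females, camera adjusted p = 9.54e-05), with Adora2a at −0.32 and Drd2 at −0.24 (edgeR adjusted p = 0.577 each). So did 8 other lists, from the ribosomal (9.54e-05) to the dopamine and cAMP list (0.0226), and all 9 had adjusted p = 0.577 with an estimated correlation. Without D2 male fentanyl 1 and D2 female fentanyl 1 together, 10 lists passed in males and 14 between the sexes in place of 6 and 9, and the cholinergic and nuclear noncoding lists of males had adjusted p = 0.0829 and 0.0547.

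The difference in fentanyl response between D1 and D2 neurons was tested in all 48 libraries. No gene of 18270 passed edgeR (825 unadjusted) or voom (1261 unadjusted), and DESeq2 called 6 (847 unadjusted), including Tpx2 (log2 0.64, DESeq2 adjusted p = 0.0285), Kcnj11 (−0.29, 0.0312) and Hnrnpu (2.92, 0.0285). Hnrnpu stood at 22.2 CPM in D1 male fentanyl 5, 31.3 in D1 female fentanyl 4 and 38.8 in D2 female water 2, and at 8.71 or below in every other library. The other 3, Psmd10, Cep170b and Gm28437, were named after their values were seen, and Gm28437 switched on in few libraries. Rprm stood at −0.47 and Zhx3 at −0.18, with edgeR adjusted p = 0.339 and 0.706. Camera called 4 lists. Of the ribosomal genes 44 of 46 were lower in the D1 than in the D2 response (adjusted p = 9.12e-07), as were 30 of 34 channel genes (0.000665) and 34 of 44 respiratory genes (0.0483), and 11 of 12 oligodendrocyte genes were higher (0.0122). All 4 had adjusted p = 0.723 with an estimated correlation. The respiratory list had 0.269 without D1 female water 6, and without D2 male fentanyl 1 and D2 female fentanyl 1 the respiratory and oligodendrocyte lists had 0.106 and 0.06. Across 16510 genes the fold changes of D1 and D2 neurons had r = 0.00381 (Spearman −0.00194, permutation p = 0.95). Those of males and females had r = 0.0293 in D1 (Spearman −0.0045, permutation p = 0.772) and −0.0957 in D2 (Spearman −0.0934, permutation p = 0.218). The adjusted p of the 3 correlations was 0.95, 0.95 and 0.654, by 100 permutations of treatment labels. Among 9144 genes with a mean CPM of at least 10 the correlations were −0.17 between D1 and D2, 0.0834 between D1 males and females and −0.545 between D2 males and females. In a test added after the data were seen, permuted labels gave −0.0206 (SD 0.25), 0.0195 (SD 0.281) and −0.0346 (SD 0.307) on average. The permutation p was 0.455, 0.842 and 0.0693 (adjusted p = 0.682, 0.842 and 0.208). Genes are not independent replicates in such a correlation.

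Females and males were compared in water libraries as a check of the labels and for baseline differences. In D1 neurons edgeR called 3 genes higher and 5 lower in females (1051 unadjusted). Uty, a Y-linked demethylase, had 0 reads in all 6 D1 female water libraries and 7.73 ± 1.17 CPM in males (SD), at least 399-fold higher against a floor of 3 reads over the group. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d stood at 62 ± 4.01, 27.5 and 10.5 CPM in D1 males and at 0.0228, 0.0305 and 0.0283 in females, and Xist, the noncoding RNA that silences an X chromosome, at 0.224 and 9.7 ± 6.52. Eif2s3x, an X-linked initiation factor that escapes silencing, was higher in females by 0.69 on the log2 scale in D1 (edgeR adjusted p = 5.32e-07) and 0.52 in D2 (1.02e-08), although 36.1% of its 50-base stretches occur in another gene. In D2 neurons edgeR called 6 genes higher and 9 lower in females (2002 unadjusted). Beyond the sex-linked genes, Xbp1, the transcription factor of the unfolded protein response (0.36, adjusted p = 0.0209), and the cochaperone Dnajb5 (0.34, 0.00583) were higher in D2 females and Ank3 lower (−0.29, 0.0209 by edgeR). With all 48 libraries in 1 edgeR fit Xbp1, Dnajb5 and Ank3 had adjusted p = 0.0633, 0.862 and 0.528, and Ank3 had 0.0571 with replicate number as a block and 0.063 with surrogate variables. The lower Ank3 here and its higher value with fentanyl in D2 females share the D2 female water libraries. The other genes that passed were named after their values were seen: ENSMUSG00000095041 (higher) and Gm29650 (lower) in both cell types, and 5530601H04Rik (higher), Gm4017, CT010467.1 and Gm49602 (lower) in D2. Voom called 11 genes in D1 and 24 in D2, and DESeq2 13 and 97.

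The Y-linked and Xist list passed camera in D1 (adjusted p = 1.16e-58, and 3.5e-07 with an estimated correlation) and in D2 (adjusted p = 5.05e-17 with an estimated correlation). In D1 water libraries 14 of 16 immediate early genes lay above 0 in females, with Nr4a1 at 0.77 and Arc at 0.54 (camera adjusted p = 7.19e-07, and adjusted p = 0.603 with an estimated correlation). This difference, the rise with fentanyl in D1 males and the sex difference in response all use the D1 male water libraries. That group had the lowest list mean in D1, 4.894 ± 0.0879 log2 CPM (SD, n = 6), so these are not separate findings. The chromatin (0.00269), channel (0.0177), circadian (0.0271) and ribosomal lists (0.0271) also lay above 0 and the oligodendrocyte (0.00187) and cholesterol lists (0.00397) below. These 6 lists had adjusted p from 0.607 to 0.803 with an estimated correlation. In D2 15 of 18 unfolded protein genes lay above 0 in females (1.59e-05, and 0.124 with an estimated correlation), and adjusted over the list alone 6 were higher, among them Xbp1, Hspa5, the chaperone BiP (0.28), and Pdia4 (0.25). Of 46 ribosomal genes 43 lay below 0 in D2 females (2.06e-12), 12 of them passing by edgeR adjusted over the list alone, including Rpl41 (−0.35) and Rpl37 (−0.22), although 27.7% and 26.1% of their 50-base stretches occur in other genes. The ribosomal rise with fentanyl in D2 females uses the same D2 female water libraries, so it is not a separate finding. The respiratory (0.00017) and channel lists (0.00595) also lay below 0 in D2 females and the cholesterol (0.00705) and immediate early lists (0.00859) above. With an estimated correlation these lists and the ribosomal list had adjusted p from 0.916 to 0.963. Over all lists, adjusted over the list alone, 8 genes passed in D1 and 34 in D2. Without D1 female water 6, 4 lists passed in D1, and the circadian, channel, chromatin, ribosomal and cholesterol lists had adjusted p = 0.0776, 0.46, 0.0776, 0.311 and 0.181, the ribosomal list with its direction turned.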

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

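Of the tests in this part, those on the Y-linked reads and on the other cell types in D2 libraries were chosen after the result was seen. Among 200 groups of 6 libraries of a named gene, 17 held a library far from the rest, where chance gives about 1 in 20 groups, here 10.

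Y-linked reads stood out in 1 female library. The other female libraries held at most 12 reads of Ddx3y, 5 of Eif2s3y, 6 of Kdm5d and 2 of Uty. D1 female fentanyl 5 held Ddx3y at 3.51 CPM against 0.105 to 0.313 in the other libraries of its group, and 189 reads of 4 Y-linked genes in all, 6% of the male level, with Xist at 175 reads against 111 to 136 in the other libraries of its group. Male RNA mixed into this pool would bring these genes in male proportions, and they stood at 4.45% (Eif2s3y) to 11.4% (Kdm5d) of the male level. Among D1 male libraries thinned to the same reads, a share of 0.00217 lay as far from the male mean with counting error alone, and 0.23 with the spread that genes at this level show between libraries. Male RNA therefore stays open as a possible source, since amplification of few molecules could give such proportions. No biological explanation was tested. Xist also had 17 and 18 reads in D1 male water 4 and D1 male water 5, and at most 11 in the other male libraries. D1 female water libraries held 140 to 399 Xist reads. The source of the Xist reads in males was not tested.

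Some genes switched on or off by more than 20-fold in single or several libraries of a cell type. With Y-linked genes and Xist left out these were 23 genes, with 68 switches on and 52 off. Reads shared with a near-identical gene copy may account for most of them, since a median of 95.6% of their transcript stretches of 50 bases also occur in another gene, against 0.224% in 228 genes matched on level. Of the 23 genes 15 are pseudogenes and 3 are encoded in mitochondria. Switches were not more frequent in fentanyl abstinence, with 2.08 per fentanyl library and 2.92 per water library (SD 2.55, permutation p = 0.301). Several of these genes switched on together in the same libraries, and the spread is wide, so this count does not exclude fentanyl as a cause. Rpl7a-ps11 at 38.7 CPM in D2 male fentanyl 6, against 0.374 to 0.778 in the others, is 1 of these genes, whereas Hnrnpu, at 22.2 CPM in D1 male fentanyl 5 (others 1.81 to 2.85) and 31.3 in D1 female fentanyl 4 (others 1.76 to 8.71), shares 0% of its stretches with another gene and its jumps stay open.

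Glial, vascular and blood transcripts were higher in D2 than in D1 libraries. Unbound RNA of all other cells carried into the D2 libraries would raise every other cell type there. Cholinergic interneuron, GABA interneuron and pallial genes were 2.04, 1.67 and 1.55 log2 units higher in D1. Such differences also depend on what the D1 libraries hold, so they do not decide whether unbound RNA entered the D2 libraries. Recombination outside neurons in the D2 driver line cannot be told apart from other differences, because mouse line and cell type are the same split, and all 24 pairs of 6 lists and 4 groups had the D2 mean above the D1 mean. A difference in cell types captured that belongs to the biology of the lines was not tested and stays open.

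Tpx2 stood at 4.67 CPM in D1 male water 6, with the others at 2.28 to 2.9. Smpd2 stood at 11.6 CPM in D1 male fentanyl 4 (others 9.7 to 9.89) and at 10.7 in D1 male water 3 (others 9.2 to 9.64). Styx stood at 4.55 CPM in D1 male fentanyl 5, with the others at 4.01 to 4.21. Drd1 stood at 603 CPM in D1 male water 1, with the others at 429 to 482. Rpl22, the tagged gene, stood at 44.7 CPM in D1 male water 3 (others 30.2 to 35.1), 43.9 in D1 female fentanyl 5 (others 30.5 to 34.3) and 57.1 in D1 female water 6 (others 29 to 38.6). In D2 libraries Tma7 was at 54.9 CPM in male fentanyl 3 (others 62.7 to 67.3). Arpc5l was at 198 CPM in D2 male fentanyl 2 (others 182 to 187) and at 184 in D2 female water 1 (others 173 to 177). Dlx1 was at 12.3 CPM in D2 female fentanyl 5 (others 16.5 to 18.8), and Lix1 at 28.8 CPM in D2 female water 4 (others 20.4 to 23.4).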

How the results depend on the processing

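The tests without single libraries, with the other cell type's marker score and by permutation of list scores were chosen after seeing the data. RLE scaling kept the counts of genes within 1.5 times and reversed no named gene, and lists were not run under it. The replicate block kept the counts of genes and lists within 1.5 times and reversed no gene or list, and under it 14 genes in place of 15 passed for sex in D2 and Ank3 had an adjusted p of 0.0571. With the block the cholinergic and dopamine lists of D2 males had adjusted p = 0.0552 and 0.0568, the respiratory list of the difference between cell types 0.0685 and the opioid list of D1 against D2 0.0826. The replicate numbers did not pair the libraries: 13 of 36 pairs in D1 and 10 of 36 in D2 had a correlation above 0.1, and the best match bore the same number in 8 and 12 of 72 cases where chance gives 12.

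Counts of genes moved as follows, and the cause was not tested. DESeq2 called 3 genes for fentanyl in D1, 4 in D1 males, 4 for the D1 sex difference in response, 1 in D2 males, 4 in D2 females, 8 for the D2 sex difference in response and 6 for the difference between cell types, where edgeR called 0. For sex in water it called 13 in D1 and 97 in D2. Voom called 2 in D1 males, 1 in D2 females and 24 for sex in D2. With all 48 libraries in 1 fit, 1 gene passed in D2 males and 1 for the D2 sex difference in response. No filter gave 1 gene in D2 females, surrogate variables 16 for sex in D1, and the other cell type's marker score 1 in D1 males (Rcor3). With the non-neuronal score 1402 genes separated D1 from D2. DESeq2 gave no adjusted p for 8 named results.

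Counts of lists rested on the correlation assumed between genes. With an estimated correlation 0 lists passed in any of the 9 fentanyl comparisons, 1 for sex in each cell type and 15 for D1 against D2. Permutation of list scores left 1 list for fentanyl in D1 and 0 in the other fentanyl and sex comparisons. Where 6 libraries stand against 6, the smallest exact p is 0.00216, or 0.0801 adjusted over 37 lists for a single list, so that in these comparisons a single list could not pass. Without D1 female water 6, 2 lists passed for fentanyl in D1 and 4 for sex in D1, where the ribosomal list turned (adjusted p = 0.311). Without D2 male fentanyl 1 and D2 female fentanyl 1, 4 lists passed for fentanyl in D2, 10 in D2 males and 14 for the D2 sex difference in response. With the non-neuronal score 14 lists separated D1 from D2, and the oligodendrocyte (adjusted p = 0.479), precursor (0.881), microglial (0.000525), interferon (0.821), matrix (0.479) and respiratory lists (0.347) reversed. The score is itself built from glial and vascular markers and nearly repeats the cell type. Its effect on D1 against D2 therefore cannot be told apart from the cell type. Of the other lists, 9 no longer passed with it: astrocyte (0.967), cholinergic (0.652), opioid (0.881), endocannabinoid (0.0738), glutamate receptor (0.243), GABA receptor (0.215), dendrite (0.0727), vesicle (0.0689) and chromatin (0.246). In D1 the blood and nuclear noncoding lists had adjusted p = 0.0506 and 0.0747 with the non-neuronal score, and the blood and ribosomal lists 0.0753 and 0.162 with the other cell type's score. In D2 the oligodendrocyte and matrix lists had 0.237 each with the non-neuronal score and the interferon list 0.0622 with the other cell type's score. In single sexes the astrocyte list of D2 females had 0.158 and the cholinergic, pallial and dopamine lists of D2 males 0.0543, 0.0813 and 0.101 with the non-neuronal score, and the respiratory list of D1 males 0.186 with the other cell type's score. For sex in D1 the oligodendrocyte and circadian lists had 0.196 each with the non-neuronal score.

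Small fold changes reversed, none of them past the threshold. For fentanyl in D1, Adora2a stood at −0.0258 with the non-neuronal score, −0.0312 with surrogate variables, −0.123 with the other cell type's score and −0.0516 without D1 female water 6. Drd2 in D1 stood at −0.0126 by voom, −0.0435 with the non-neuronal score, −0.0929 with the other cell type's score and −0.0266 without D1 female water 6. Of the D1 opioid genes, Oprk1 stood at −0.0014 and Pdyn at −0.0826 with surrogate variables, and Oprd1 at −0.0303 with the other cell type's score. In D2, Adora2a stood at −0.0175 with the non-neuronal score, −0.0422 with surrogate variables and −0.0407 without D2 male fentanyl 1 and D2 female fentanyl 1. Oprm1 in D2 stood at 0.0122 by voom and 0.06 without those libraries, Pdyn at −0.0118 without them and Pnoc at 0.00502 by voom. Among genes with a mean CPM of at least 10 the correlation of fold changes was −0.17 between D1 and D2, 0.0834 between D1 males and females and −0.545 between D2 males and females. The median half-width of the log2 interval was 0.382 for the D1 and 0.306 for the D2 sex difference in response, and how much of it depth accounts for was not tested.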

Other observations

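The tests in this part on splits of the libraries were chosen after the results were seen, as was Xist as a gene to examine.

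Xist, the RNA of the silenced X chromosome, stood lower with fentanyl than with water in females of both cell types. In D1 females it was at 5.02 ± 0.686 CPM with fentanyl and 9.7 ± 6.52 with water (SD, log2 −0.93, SE 0.422, adjusted p = 0.862 by edgeR). In D2 females it was at 5.31 ± 0.799 and 9.94 ± 3.49 CPM (log2 −0.91, SE 0.264, adjusted p = 0.854 by edgeR). Neither difference passed. D1 female water 6 stood at 22 CPM, and without it the D1 difference was −0.53 (edgeR adjusted p = 0.868). Without the same library the nuclear noncoding list of D1 neurons no longer passed camera (adjusted p = 0.0561).

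Reads assigned to Lars2, the gene of a mitochondrial leucyl-tRNA synthetase, made up 3.5 ± 0.663% of gene reads in D1 and 1.565 ± 0.213% in D2 libraries (SD, n = 24 each), and 5.81% in D1 female water 6. That library had 20211543 reads in genes, the fewest of all, with 67.4% of its reads in genes and 17.5% outside exons. Whether the reads assigned to Lars2 come from its messenger RNA was not tested.

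The libraries were split at random within the design 100 times and refitted beside the real split. For fentanyl edgeR called 0 genes, so that all 101 splits must give as many and the counts decide nothing about chance. The highest count of the other splits was 8 in D1, 0 in D1 males, 2 in D1 females, 2 for the D1 sex difference in response, 147 in D2, 49 in D2 males, 0 in D2 females, 5 for the D2 sex difference in response and 3 for the difference between cell types. Splits of D2 libraries that call 147 and 49 genes point to a structure of the samples, and what it is was not tested. D1 libraries also stood apart on the first principal component of their log2 CPM (15.1% of variance). D1 male fentanyl 1, male water 2, male water 3, female fentanyl 4, female fentanyl 5 and female water 6 lay at −54 to −21.8. All other D1 libraries lay at −2.69 or above. Whether this widens the D1 intervals was not tested. With 2 surrogate variables edgeR called 0 genes for fentanyl in D1. For the counts of lists, chance could not be excluded either: 57 of 101 splits gave as many as the real 6 lists in D1 (highest other 19), 65 as many as the real 7 in D2 (highest other 20) and 81 as many as the real 4 for the difference between cell types (highest other 15). For sex in water no drawn split gave as many as the 8 genes called in D1 (1 of 101 splits, highest other 2). Most of these are sex-linked genes, which must follow correct labels, so this says little about other genes. In D2, with 15 genes, 2 of 101 splits gave as many, but the highest other split called 35, so that the count alone does not set the real split apart. For D1 against D2 no drawn split gave as many as the 9758 genes of the real split (1 of 101 splits, highest other 3751, which points to the cell types as a structure of the samples).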
